A study of Homo sapiens with 4 samples.

How the data were processed

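Total RNA was measured on 4 Affymetrix expression arrays, 1 for each of 4 groups. The groups cross 2 derivatives of the ovarian cancer line SKOV/ip, one carrying a mock construct (Fumock) and one carrying FuEP2/Ex2, with 2 growth settings, cultured cells and the tumours that formed after intraperitoneal injection and 4 weeks of observation. What FuEP2/Ex2 encodes and the host species are not given in the sources used here. RNA was extracted on silica columns, labelled with biotin and prepared with a whole-transcript kit, per the labels' protocols. Groups were taken from the sample titles. With 1 array per group the number of arrays limits the precision, no spread between replicates could be measured, and no replicate could be left out.

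The deposited values are linear intensities, 1 per probe set and array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The version, the background correction and the summarization method are not given in the sources used here. The deposited intensities were positive, not centred per gene and not on a log scale. Their medians over 33297 probe sets were 136 in mock cells, 134 in FuEP2/Ex2 cells, 156 in the mock tumour and 154 in the FuEP2/Ex2 tumour. The tumour arrays thus had higher medians than the cell arrays. The arrays were nevertheless used as deposited, without a further scaling in the main setting.

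Intensities below the 5th percentile of all values, 10.2, were set to that floor, and log2 was taken. Of the probe sets, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 were not listed. Genes were named only from the first kind, and 19429 of their gene identifiers were found in a reference table of human genes (assembly GRCh38.p14), which updated 0 symbols. This left 18417 genes. The 769 genes with several probe sets were represented by the probe set with the highest mean.

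Every pairwise difference is a difference of log2 intensities between 2 arrays. A gene was compared only where the higher of its 2 values was at or above that array's median over named genes, and it was counted where it differed 2-fold or more. These counts rest on size and carry no p-value. For the difference of differences, the construct difference in cells was subtracted from that in tumours. Overlaps of counted genes were set beside the overlap of independent lists.

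The only test with an error among samples was an additive fit of construct and growth setting in limma 3.58.1 (R 4.3.3), with moderated variances, an intensity trend and Benjamini-Hochberg adjustment. It ran on 9209 genes with a mean at or above the median of gene means. It has 1 residual degree of freedom per gene, which takes the difference of differences as error. Nothing in the labels says that arrays differ only by chance in that term, so its p-values assume that construct and growth setting act additively. The 2 arrays of a construct are the cells and the tumour of the same line, not independent replicates of the construct. On simulated data with 200 changed genes among 9209, the construct term recovered 96.6% of 2-fold and 100% of 4-fold changes. False calls made up 11.6% of all calls on average, from 3.05% to 35.4% over 20 simulated sets. They made up 5.23% when the prior variance and its degrees of freedom were known. The adjusted p-values are thus too small on average.

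Before the data were examined, 27 gene groups and 13 cell type marker lists were fixed. A list's median difference was given with its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. A list stands apart where that percentile is at or below 2.5 or at or above 97.5. This describes these arrays and is not a test. In simulated lists of 20 genes, 6.5% stood apart without a shift, 89.5% with a shift of 0.4 log2 and 100% with a shift of 0.6 log2. A bar of 90% set for the 0.4 shift without a power calculation was missed, and was replaced by the range expected from the median's standard error, 85.7% to 94.6%. The size rule counted all 200 of 200 simulated 4-fold changes.

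The genes named were also fixed by rule. They are the 10 highest and 10 lowest in each construct difference, up to 10 per direction in each shared difference, the 5 highest and 5 lowest in the difference of differences, up to 4 members of a list described, any cell type marker, and reference genes including ERBB2 and EGFR. Small RNA genes, olfactory receptors and unnamed loci were left out of the ranked genes. Alternatives were centring, quantile normalization (limma), cyclic loess (limma), the signal filter, the fold, the mean of a gene's probe sets and, for the fit, no intensity trend. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

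After the data were examined, 3 further lists (amino acid response, endoplasmic reticulum chaperones, tRNA synthetases) and a scan of neighbouring genes were added. The scan took running medians over 41 expressed genes in the gene order of the reference table, and compared them with 1000 shuffled orders. Zinc finger genes were taken as those whose symbols begin with ZNF, ZFP or ZSCAN. The array's genome build is not given in the sources used here, so no coordinates are printed. On simulated maps the scan found 10 of 10 planted blocks, and 1 of 10 maps without a block passed its threshold.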

Results

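Gene expression was measured in SKOV/ip, a line derived from the SKOV-3 ovarian cancer cells, carrying either a mock construct or FuEP2/Ex2. Each line was profiled as cultured cells and as a tumour formed after intraperitoneal injection, with 1 array for each of the 4 groups. There were no replicates, so every pairwise value below is a difference between 2 arrays. Array pairs of one growth setting correlated at 0.984 across genes in cells and 0.985 in tumours, and tumour and cells of one line at 0.968 (mock) and 0.972 (FuEP2/Ex2). ERBB2, the receptor amplified in SKOV-3, had intensities of 10700 in mock cells, 10200 in FuEP2/Ex2 cells, 11600 in the mock tumour and 11500 in the FuEP2/Ex2 tumour. EGFR lay between 890 and 1270 on the 4 arrays. The median of the housekeeping genes did not stand apart in any comparison.

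The first comparison asked which genes differed between the lines in culture. PEG10, a retrotransposon-derived imprinted gene, was 13.5-fold higher in FuEP2/Ex2 cells (log2 difference 3.76), and SERPINB5, which encodes the serpin maspin, was 14.6-fold higher (3.87). DPYSL5 (2.34), LUM (2.34), VSNL1 (2.27), the cadherin CDH6 (2.18), SEPTIN3 (2.14), RAMP2 (2.12), HSPA2 (2.12) and KCNMB4 (2.05) followed. The lowest values relative to mock cells belonged to the cancer-testis gene MAGEB2 (-5.32), HAVCR1 (-4.71), the transcriptional cofactor ZFPM2 (-3.70) and PLAC8 (-3.55). PTGS2, the inducible cyclooxygenase, was lower by -3.28, and CHAC1, which degrades glutathione, by -3.01. VNN2 (-2.99), the EGFR ligand EREG (-2.91), the chemokine CCL20 (-2.83) and MME (-2.79) completed the 10 lowest. In all, 149 genes were higher and 118 lower by 2-fold or more among 9642 compared.

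Inflammatory cytokines and chemokines were lower in FuEP2/Ex2 cells, with a list median of -0.75 over 19 genes (percentile 0.00). Of the 13 members compared, 6 were lower by 2-fold or more and 0 higher. Their differences included -2.24 for IL6, -2.13 for IL1B and -1.91 for IL1A. DNA replication genes stood apart as higher, with a median of 0.66 (percentile 100), led by CDC6 (1.18) and TYMS (1.12), the 2 of 20 members that were higher by 2-fold. Genes of the cell cycle and mitosis had a median of 0.43 (percentile 100) with 0 of 20 members past 2-fold, and TOP2A was at 0.74 and KIF11 at 0.73. The unfolded protein response list had a median of -0.31 (percentile 0.00), and 6 of its 17 compared members were lower by 2-fold, including CHAC1, DDIT3 (-2.12), ASNS (-1.82) and TRIB3 (-1.70). ASNS, which makes asparagine, CHAC1, DDIT3 and TRIB3 are also known targets of the response to amino acid shortage. Heat shock genes (0.30), interferon response genes (0.26), epithelial genes (0.19) and oxidative phosphorylation genes (0.19) stood apart as higher. Cholesterol biosynthesis (-0.23) and extracellular matrix genes (-0.19) stood apart as lower. The matrix list held opposite members, with fibronectin (FN1) at -2.68 and lumican (LUM) at 2.34. The interferon, oxidative phosphorylation and matrix lists no longer stood apart when members below the array median on both arrays were left out. The other 17 gene groups had medians between -0.10 and 0.14 and did not stand apart, nor did any of the 13 cell type marker lists.

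In tumours, the comparison that the series title names, PEG10 was highest in FuEP2/Ex2 (log2 difference 2.98, 7.91-fold). ADGRG2 (2.44), the membrane protease TMPRSS4 (2.23), the matrix metalloproteinase MMP7 (2.20), CYP1B1 (2.06), ARRDC4 (2.02), GRPR (1.89), SEPTIN3 (1.77), AQP7 (1.73) and the myosin MYO5B (1.71) came next. ANPEP, an aminopeptidase, was lowest (-3.63), ahead of ZFPM2 (-3.31), HAVCR1 (-3.04), MAGEB2 (-2.91), TMTC1 (-2.48) and tenascin C (TNC, -2.40). NDNF (-2.19), MFAP5 (-2.05), LDOC1 (-1.87) and GAL3ST1 (-1.84) were also among the 10 lowest. In total 87 genes were higher and 73 lower among 9694 compared.

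Epithelial genes stood apart as higher in the FuEP2/Ex2 tumour, with a median of 0.35 over 17 genes (percentile 100). CDH3 was at 1.62, EPCAM at 1.19, CDH1 (E-cadherin) at 0.91 and CLDN4 at 0.64, and 2 of 14 compared members passed 2-fold. In cells CDH1 had the opposite sign (-1.04). Inflammatory genes again stood apart as lower (median -0.39, percentile 0.00; 2 of 12 compared members lower by 2-fold), with IL6 at -1.73, CXCL2 at -1.20, CXCL8 at -0.95 and CXCL1 at -0.92. Interferon response genes stood apart as lower by their median (-0.23, percentile 0.19), where it was 0.26 in cells, but 1 of 10 compared members was lower by 2-fold here and 0 of 9 higher in cells. Members were OAS2 at -1.11, OAS1 at -0.82 and IFI6 at -0.80. TGF-beta response genes (0.26) and cell cycle genes (0.21) stood apart as higher. Cholesterol biosynthesis (-0.22), hypoxia and glycolysis (-0.18), ovarian cancer antigens (-0.17), angiogenic factors (-0.15) and the unfolded protein response (-0.15) stood apart as lower. Among the antigens, MUC16, which carries CA-125, was nevertheless higher (1.69), while SPP1 (-1.31) and CP (-1.05) were lower. The angiogenic list no longer stood apart under cyclic loess or quantile normalization. Of the cell type markers, the neutrophil list stood apart as lower (-0.28, percentile 2.28), but not under cyclic loess, with 1 of its 11 genes passing the signal filter.

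The construct differences in cells and in tumours use different arrays. In the same direction in both, 35 genes were higher and 24 lower by 2-fold or more among 9038, against 0.97 and 0.55 for independent lists. The differences correlated across genes at r = 0.5 (rho = 0.421), and genes are not independent replicates. Beside PEG10, SEPTIN3, MYO5B and LUM, the higher genes included the KIT ligand KITLG (1.76 in cells, 1.5 in tumours), MUC16 (1.44 and 1.69) and CYP2S1 (1.38 and 1.37). Beside ZFPM2, HAVCR1 and MAGEB2, the lower genes included the lipid droplet protein PLIN2 (-2.29 and -1.81), IL6 (-2.24 and -1.73), FN1 (-2.68 and -1.66), the angiopoietin ANGPT2 (-2.34 and -1.56), RNF182 (-1.94 and -1.55), PTX3 (-1.49 and -1.81) and FMN1 (-2.66 and -1.42). CYP2S1 lies in a run of 21 windows of neighbouring genes that were higher, and PTX3 in a run of 174 windows that were lower. FMN1 is the centre of a lower run of 1 window.

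**Figure D1:**
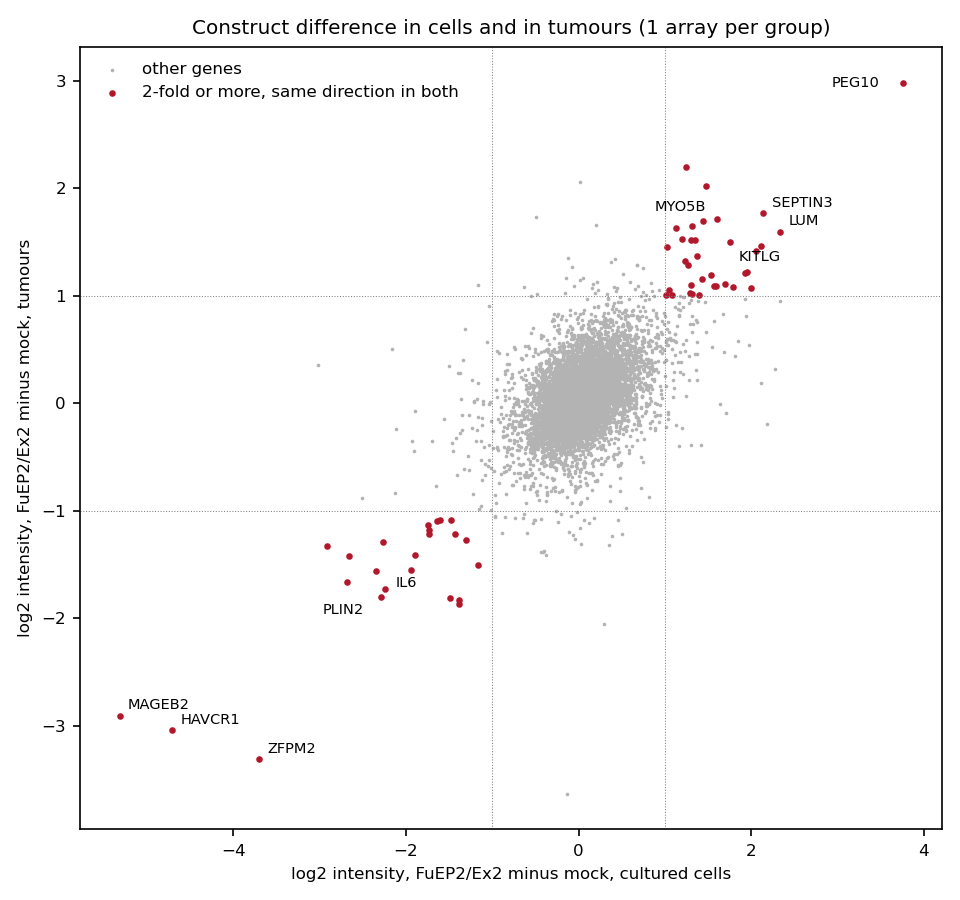
Each point is a gene compared in both growth settings, with the log2 intensity difference, FuEP2/Ex2 minus mock, in cultured cells on the x axis and in tumours on the y axis. Red points are the 35 genes higher and 24 genes lower by 2-fold or more in both, dotted lines mark 2-fold, and PEG10 lies at the upper right and ZFPM2, HAVCR1 and MAGEB2 at the lower left, away from the other red points.

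In the additive fit over all 4 arrays, the construct term passed an adjusted p of 0.05 for 150 genes higher and 73 lower in FuEP2/Ex2 among 9209 tested. ZFPM2 fell by 3.51 on the log2 scale (SE 0.156, limma adjusted p = 7.23e-05) and PEG10 rose by 3.37 (SE 0.19, adjusted p = 0.000257). IL6 fell by 1.99 (SE 0.161, adjusted p = 0.00257) and EPCAM rose by 1.36 (SE 0.141, adjusted p = 0.00403). Both arrays of a construct come from the same line, so this term cannot separate the construct from other differences between the 2 lines. ERBB2 and EGFR did not pass (adjusted p = 0.837 and 0.905). The count is fragile: it was 4 under quantile normalization and 0 without the signal filter, where 2619 genes had an unadjusted p under 0.05. The share of higher genes was 67.3%, and 56.9% with each array centred and 58.5% under cyclic loess. Under quantile normalization it was 50%, but of 4 genes.

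Tumours were next compared with cultured cells of the same line. SLC14A1, a urea transporter, was 51.5-fold higher in the mock tumour and 64.0-fold higher in the FuEP2/Ex2 tumour (log2 5.69 and 6.0). NOSTRIN (4.08 and 4.08), the proteoglycan biglycan (BGN, 4.08 and 3.53), SHISA3 (4.25 and 3.22), the lipase LIPG (3.09 and 3.94), CXADR (3.0 and 3.53) and GRPR (2.63 and 4.04) were higher in both. AMTN (-5.27 and -5.75), CYP24A1, which inactivates vitamin D (-5.15 and -3.90), EDIL3 (-4.39 and -4.00), EFEMP1 (-3.32 and -4.03), the collagenase MMP13 (-2.86 and -3.04), LCN2 (-2.69 and -2.86) and endothelin EDN1 (-3.98 and -2.58) were lower in both. In the mock line 182 genes were higher and 522 lower among 9862, and in the FuEP2/Ex2 line 188 and 353 among 9788. Both lines shared 104 higher and 198 lower genes among 9350, against 2.72 and 15.88 for independent lists (r = 0.764, rho = 0.687 across genes).

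Hypoxia and glycolysis genes stood apart as higher in tumours, with medians of 0.36 in the mock line and 0.25 in the FuEP2/Ex2 line (percentile 100 in both), and 3 and 4 of 18 compared members higher by 2-fold. EGLN3, an oxygen-sensing hydroxylase, was at 1.52 in the mock line and 2.36 in the FuEP2/Ex2 line. Inflammatory genes were lower, with medians of -1.21 and -0.44. In the mock line 11 of 13 compared members were lower by 2-fold, including IL6 (-2.76) and CCL20 (-2.30), and in the FuEP2/Ex2 line 7 of 12, while 5 and 7 of all 19 members had positive values. TGF-beta response genes stood apart as lower in both (-0.73 and -0.40; 5 and 4 of 18 compared members lower by 2-fold), led by ID3 (-3.46 and -2.17) and ID1 (-1.88 and -1.47). Cell cycle genes stood apart as lower by their medians (-0.47 and -0.72, against -0.24 for matched random lists in both), with 0 and 1 of 20 members lower by 2-fold. So did replication-dependent histones (-0.33 and -0.38), with 1 of 11 and 0 of 13, but not in the mock line without members below the array median on both arrays. Immediate early genes stood apart as higher by their medians (0.26 and 0.13), but of 13 compared members 2 were higher and 3 lower by 2-fold in the mock line and 1 higher and 1 lower in the FuEP2/Ex2 line. EGR1 was at 2.08 and 1.65, MYC at -1.05 in the mock line and JUNB at -1.05 in the FuEP2/Ex2 line. Mesenchymal genes stood apart as higher by their medians (0.07 and 0.05), while their means were negative (-0.12 and -0.10), with CDH2 (N-cadherin) at -2.37 and -2.01, and they no longer stood apart in the mock line under cyclic loess or in the FuEP2/Ex2 line with the mean of a gene's probe sets. DNA replication genes were at 0.08 in the mock line, above matched random lists (-0.22), and at -0.44 in the FuEP2/Ex2 line. The unfolded protein response stood apart in the mock line (-0.52), with 7 of 17 compared members lower by 2-fold, and not in the FuEP2/Ex2 line, with 0 of 15. The mock cell array enters both the mock tumour-minus-cell difference and the one between the lines in cells. This holds for every list, the inflammatory and DNA replication genes included, so these are not separate observations. In the FuEP2/Ex2 line interferon (-0.48) and heat shock genes (-0.43) stood apart as lower, with 1 of 9 and 2 of 15 compared members lower by 2-fold, and extracellular matrix (0.22) and ERBB genes (0.16) stood apart as higher by their medians. The matrix list had a mean of 0.03, with 10 positive and 8 negative values, and held THBS1 at -2.44 and FBN1 at -2.35. Of 14 compared ERBB genes 3 were higher and 1 lower by 2-fold, with ERBB4 at 3.22, the ERK phosphatase DUSP6 at 2.31 and NRG1 at -1.54. The heat shock, immediate early and ERBB lists of the FuEP2/Ex2 line no longer stood apart under cyclic loess or quantile normalization, and the ERBB median had the opposite sign under the latter.

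Markers of other cell types gave mixed values. PECAM1, an endothelial marker, was higher in tumours of both lines (1.71 and 1.64), as were CDH5 (0.62 and 1.0) and the collagen gene COL1A2 (1.29 and 1.01), whereas the endothelial marker PLVAP was lower (-1.90 and -2.32). The fibroblast, endothelial and macrophage lists did not stand apart in either line. The neutrophil list stood apart in the mock line (0.53, percentile 99.9), and the mesothelial (0.35) and hepatocyte lists (0.34) in the FuEP2/Ex2 line. Of these, 1 of 11 neutrophil, 3 of 9 mesothelial and 2 of 10 hepatocyte genes passed the signal filter. Under quantile normalization the mesothelial and hepatocyte lists no longer stood apart.

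In the additive fit the growth setting term passed for 500 genes higher and 2447 lower in tumours, including SLC14A1, which rose by 5.84 (SE 0.146, limma adjusted p = 5.78e-07). These 2947 calls became 1480 under quantile normalization and 934 without the signal filter. Over compared genes the median tumour-minus-cell difference was -0.21 in both lines as deposited and -0.07 in both under cyclic loess, so part of the excess of lower genes moves with the scaling. The share of higher genes in the growth term was 17.0%, and 36.0% under cyclic loess and 29.4% under quantile normalization.

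**Figure D2:**
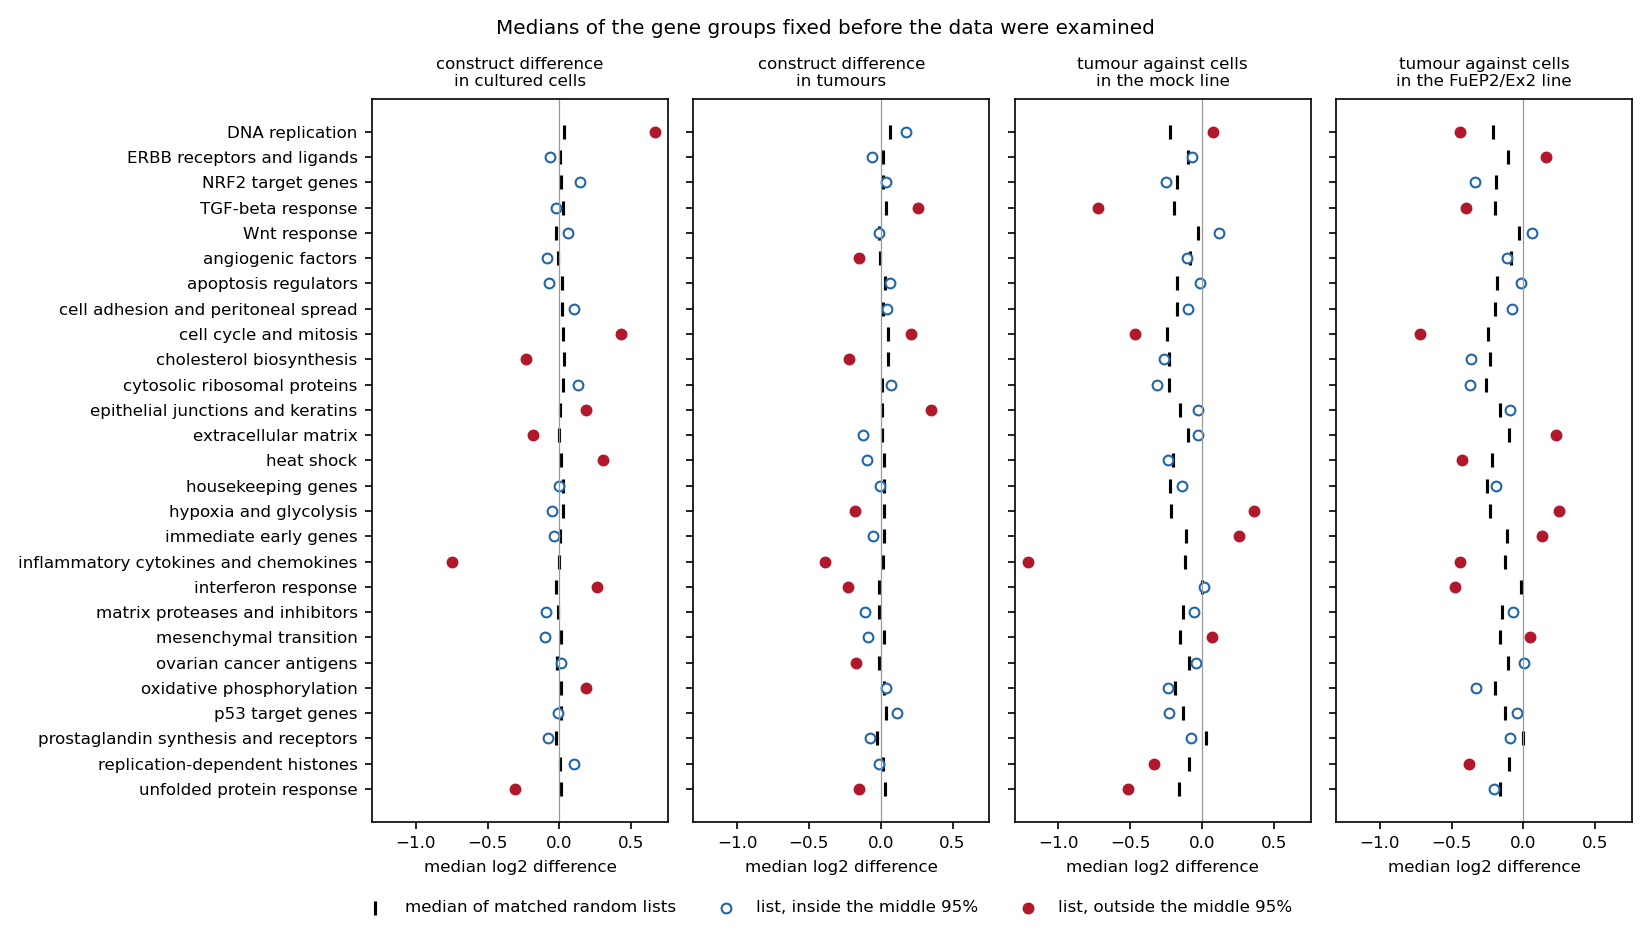
Each row is a gene group and each panel a comparison, with the list's median log2 difference on the x axis as a circle, filled where it lies outside the middle 95% of matched random lists, and a bar at the median of those random lists. Inflammatory genes lie furthest left in cells (-0.75) and in the mock tumour against its cells (-1.21). Both differences use the mock cell array.

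The difference of differences asked where the construct difference in the tumours was not that in the cells. It was 2-fold or more for 141 genes with a higher and 100 with a lower value in tumours among 10290, with no degrees of freedom left to test it. PTGS2 (3.43), CHAC1 (3.37), VNN2 (3.33), FBXL21P (2.67) and BCAT1 (2.66) were highest. PTGS2 differed by -3.28 between the lines in cells and by 0.15 in tumours. ANPEP (-3.50), PCDH18 (-2.78), ST8SIA6 (-2.61), SERPINB5 (-2.60) and CDH6 (-2.37) were lowest. By list, interferon response (-0.59), DNA replication (-0.44), heat shock (-0.26), cell cycle (-0.21) and oxidative phosphorylation genes (-0.16) stood apart as lower, the last not under quantile normalization. The unfolded protein response (0.28), TGF-beta response (0.27) and inflammatory genes (0.19) stood apart as higher. The inflammatory list was lower in FuEP2/Ex2 in both settings (-0.75 in cells, -0.39 in tumours), as was the unfolded protein response (-0.31 and -0.15). For these lists the positive values mark a smaller deficit in tumours, not a higher level. The mock cell array enters these values too. The mesothelial (-0.44) and neutrophil (-0.25) marker lists stood apart as lower, with 3 of 9 and 1 of 11 genes passing the signal filter. Over the 4 pairwise differences, 45 of 160 list medians stood apart, 21 higher and 24 lower. The percentile limits alone would give 8 for lists of randomly drawn genes. That number is no expectation for these lists, whose members may vary together. The 4 differences also share arrays, so the 160 medians are not separate trials.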

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

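These genes differed in direction between growth settings or lines, and the differences were not tested, since each group has 1 array. TNFRSF11B, which encodes the decoy receptor osteoprotegerin, was higher in FuEP2/Ex2 than in mock tumours (log2 difference 1.1) and lower in FuEP2/Ex2 than in mock cells (-1.16). CDH6 was higher in the tumour than in cells in the mock line (1.37) and lower in the FuEP2/Ex2 line (-1.0). FBXL21P was lower in the tumour than in cells in the mock line (-1.01) and higher in the FuEP2/Ex2 line (1.65).

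Among 13837 probe sets with several genes or none, which no comparison used, 3528 passed the signal filter in cells and tumours. Of these, 1 was higher and 3 were lower in FuEP2/Ex2 by 2-fold or more in both.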

How the results depend on the processing

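The removal of the block of neighbouring genes was chosen after the data were seen, and the other alternatives before. Counts are given in the order construct in cells, construct in tumours, tumour against cells in the mock line, the same in the FuEP2/Ex2 line, difference of differences, shared construct and shared tumour against cells. They were 136, 68, 413, 301, 130, 18 and 167 with the 75th percentile as filter, which compares fewer genes. A 1.5-fold rule gave 909, 717, 2220, 1961, 976, 221 and 1055, and a 3-fold rule 74, 32, 197, 159, 55, 10 and 79, as a looser or stricter rule must. The additive fit's construct count was 4 under quantile normalization and 0 without the signal filter, and its growth count 1480 and 934. The fit's prior degrees of freedom were 7.43 in the main setting, 4.60 under quantile normalization and 3.33 without the filter, and the cause of that change was not tested. The other 52 counts stayed within 1.5 times, those without the block included (257, 157, 57 shared and 236 for the difference of differences). Of the 35 shared higher genes 2 lie in the block, so its removal could move the counts little. The other runs of neighbouring genes were left in. The balance of directions still moved. With each array centred, 124 genes were higher and 130 lower for the construct in cells, 74 and 77 in tumours, and 28 and 28 shared. Of 965 list medians under alternatives, 910 kept their side of the percentile limits, 21 no longer stood apart, 33 newly did, and 1 reversed: ERBB genes in the FuEP2/Ex2 tumour against its cells, -0.03 under quantile normalization, and the cause was not tested. The 21 belong to the mesenchymal, immediate early, heat shock, ERBB, mesothelial and hepatocyte lists in the FuEP2/Ex2 tumour against its cells, the mesenchymal and histone lists in the mock line, the matrix, interferon and oxidative phosphorylation lists between the cells, the angiogenic and neutrophil lists between the tumours, and oxidative phosphorylation in the difference of differences. Of 690 values of ranked genes, 638 stayed past 2-fold and 52 no longer met the size rule or the filter, none with a change of sign. Background signal was not measured in the values used here, so the lowest intensities have no bound.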

Other observations

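The tests of scaling, of the neighbouring genes, of an intensity-dependent difference and of host cells were chosen after the results were seen. Those of endoplasmic reticulum stress and of an amino acid response were recorded as chosen before the values they use were seen. The unfolded protein response list also holds chaperones such as HSPA5, so the endoplasmic reticulum test was not fully independent of that list.

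Genes known to respond to amino acid shortage set the mock cells apart from the other 3 arrays. The median of 21 such genes was -1.22 in FuEP2/Ex2 against mock cells, and 11 of 18 compared members were lower by 2-fold or more. PHGDH, which starts serine synthesis, was at -2.51 and the stress gene NUPR1 at -1.93. The same list was at -1.86 in the mock tumour against mock cells, where the amino acid transporter SLC7A5 was at -2.10. It did not stand apart between the tumours (-0.08) or between the FuEP2/Ex2 tumour and its cells (-0.30).

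Scaling of the mock cell array that shifts all genes of one level alike was argued against. Random lists matched on level had a median of 0.01 as deposited. Cyclic loess therefore had little to correct, and the list's median was still -1.15 under it. Stress of the endoplasmic reticulum that strongly raises its chaperones was argued against too. These had a median of -0.103 in cells (percentile 4.84, near the limit of 2.5), with 11 of 17 negative. Between the tumours the chaperones stood apart as lower (-0.145, percentile 0.78). A stress that leaves the chaperones little changed cannot be excluded, because only chaperones were used. The amino acid response list was drawn up after CHAC1, PHGDH and DDIT3 were seen. An amino acid response in the mock culture was therefore tested on 13 tRNA synthetase genes outside it that this response is known to raise. It may account for the pattern, as they were at -0.69 in cells (percentile 0.00) and 0.02 in tumours (percentile 34.79), while 6 synthetase genes not known to be raised were at 0.04 in cells. Other stresses share these targets, medium and cell density were not analysed here, and 1 culture cannot separate them from the construct.

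A block of 119 expressed genes in reference gene order, from DDX49 to NCCRP1, was higher in the FuEP2/Ex2 line, with medians of 0.31 in cells and 0.34 in tumours. It holds 40 zinc finger genes such as ZNF730 (1.70 and 1.11) and also the cyclin gene CCNE1 (0.85 and 0.48), which was singled out after its values were seen. Chance order was argued against, since the highest window, 0.521, exceeded all 1000 shuffled orders (highest 0.248). Zinc finger paralogs were argued against as the whole cause, since a scan without zinc finger genes had its highest window in the same block (0.273, highest shuffled 0.227). A difference in gene dosage between the lines may apply but stays open, because the difference of differences of the block's other 79 genes was -0.089 (percentile 0.55), outside the range set for it, and GC content was not tested.

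With this block counted, 16 higher and 25 lower runs of neighbours passed the shuffled limits. The longest was a lower run of 174 windows centred on HPS3. The runs are not all separate regions, since the genes under their windows can overlap. Those of the longest run end at GNB4, while those of a lower run of 38 windows start at NMD3, inside the longest. Runs were not grouped by chromosome or arm, so the full extent of the pattern was not measured. The correlation between adjacent genes was 0.168 for the construct difference in cells and 0.224 in tumours. It was also 0.138 and 0.131 for tumour against cells, where both arrays come from the same line.

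The cell type markers were not all absent from the cultured cells, where 5 of 15 fibroblast markers passed the signal filter between the lines. They were slightly higher in tumours (list medians 0.07 to 0.53 in the mock line, 0.06 to 0.40 in the FuEP2/Ex2 line). An intensity-dependent difference between arrays may account for much of it, since 4501 genes with low mean levels (the lowest 25%) and in no list had a median of 0.18 in the mock line and 0.14 in the FuEP2/Ex2 line. Host cells as a further source stay open: the fibroblast, endothelial and macrophage lists reached percentile 94.52 at most. Single markers went both ways, with PECAM1 and COL1A2 higher in both tumours and PLVAP lower in both. By 2-fold, 1 of 5 compared fibroblast markers was higher and 0 lower in the mock line. In the FuEP2/Ex2 line 1 of 6 was higher and 2 lower. In the mock and FuEP2/Ex2 lines 12 and 9 of 15 fibroblast markers were positive. So were 12 and 13 of 15 endothelial and 9 and 10 of 15 macrophage markers. Of the 13 marker lists 3 stood apart as higher in 1 line each, neutrophil in the mock line (S100A9 at 0.37) and mesothelial (MSLN at -1.61) and hepatocyte (ALB at 0.34) in the FuEP2/Ex2 line. The host species is not given in the sources used here, and human probes can miss another species' RNA.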
